A study of Mus musculus with 20 samples.

How the data were processed

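Total RNA of hair follicle stem cells from male mice was purified with a column kit and Cy3-labelled as cDNA by the authors, and each of 20 samples was hybridised to 1 Agilent mouse array. The labels give ND and HFD for 3 months or 4 days and an aged group, each with 3 telogen arrays and 1 anagen array. How the cells were isolated is not given in the sources used here. Per the file headers, the scanner files were made with Feature Extraction 10.7.1.1 and hold background-subtracted and detrended spot intensities, with no scaling between arrays. The deposited table of the series holds a signal per probe on a linear scale, which matched the processed intensity of the same array divided by its 75th percentile, with no centring of genes. The medians of its columns were 0.111, 0.12 and 0.115 for ND 3 months telogen, 0.138, 0.143 and 0.092 for HFD 3 months, 0.128, 0.126 and 0.128 for ND 4 days, 0.152, 0.145 and 0.128 for HFD 4 days and 0.146, 0.111 and 0.168 for aged, and 0.088, 0.128, 0.13, 0.11 and 0.104 for the 5 anagen arrays in the same order.

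Each array held 59305 spots outside the controls, of which 0 were saturated and 62 to 159 were marked as outliers and set to missing. Processed intensities were averaged over the spots of a probe, put on the log2 scale, and scaled by subtracting the 75th percentile of the array. A probe was tested when well above background on all 3 arrays of at least 1 telogen group or on at least 3 of the 5 anagen arrays, which left 43395 of 56605 probes. The scanner files carry no gene symbols, so probes were matched through their transcript accessions to RefSeq symbols: 32994 probes matched 1 symbol and 23611 matched none and were left out of the gene tests. A gene was represented by its tested probe with the highest mean, giving 18727 genes.

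Telogen groups were compared in 1 limma fit over the 15 telogen arrays, and anagen with telogen in a fit over 20 arrays with condition as a factor (limma 3.58.1, R 4.3.3, jsonlite 2.0.0, and data.table at 1.17.8). limma's moderated test was two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The median half-width of the 95% interval of a log2 difference was 1.15 in the telogen comparisons of groups, 1.62 for diet by duration and 0.75 for anagen, so the number of arrays limits the precision. Gene lists, 39 with 12 sets of markers of other cell types among them, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and on ranks. Where a gene was well above background on 0 arrays of 1 group, its fold is a lower bound: the mean of the other group was set against the lowest signal called well above background on the arrays of the dim group, or an array's own value where higher, averaged over the group. Recovery was tested on simulated data with 200 genes changed by a known fold. Diet and age differences in anagen were taken between single arrays, with list medians ranked among 10000 random lists.

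The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for 2 alternatives added after seeing the data and for the tests given as chosen only after the result was seen. The rule takes up to 10 genes per direction with the largest change among those past the threshold whose groups do not overlap (for anagen against telogen, whose 5 differences within conditions share a sign), without predicted or clone names, or, where fewer than 5 pass in a direction, the 5 with the smallest p. It adds up to 4 members of each list with the smallest p among those past the threshold, further members of lists that were called, and a set of key genes for the diet and ageing comparisons. Some genes that the rule names are not reported here. The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median, a percentile over probes detected on all arrays, no filter or a stricter filter on dim probes, the mean over the probes of a gene, the series table, eBayes with a trend or robust, array weights, other sets of arrays in the fit, a replicate or a slide block, stricter thresholds, and leaving out each array. As the scanner files have no mean signal, normexp used the median signal. The slide block was fitted over all 20 arrays with condition and phase as further terms. Since the telogen arrays of a condition share 1 slide, there the slide term rests on the single anagen arrays. Slides, rows and columns were read from the array positions. All anagen arrays lay in column 1 of a slide and all telogen arrays in columns 2 to 4. The first slide held ND 3 months telogen in row 1 and HFD 3 months telogen and ND 3 months anagen in row 2. The second slide held ND 4 days telogen and HFD 3 months anagen in row 1 and HFD 4 days telogen and ND 4 days anagen in row 2. The third slide, called slide 3 and scanned separately, held aged telogen and HFD 4 days anagen in row 1 and aged anagen in row 2.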

Results

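Gene expression was measured in hair follicle stem cells, which reside in the bulge of the follicle and rebuild it at each hair cycle, from male mice. A normal diet (ND) and a high fat diet (HFD) had been fed for 3 months to mice that were 5 months old at sampling, or for 4 days to mice that were 2 months old, and a further group was 24 months old (aged). For each of these 5 conditions there were 3 arrays from telogen, the resting phase of the cycle, and 1 array from anagen, its growth phase, 20 arrays in all. Between 60.7% and 83.49% of the spots of an array were well above background, with the lowest share on the ND 3 months anagen array and the highest on an ND 4 days telogen array. Correlations across genes between telogen arrays of a group had a median of 0.905, against 0.896 for telogen arrays of different groups and 0.877 for an anagen with a telogen array. The median standard deviation of a gene within a telogen group was 0.43 (log2) in ND 3 months, 0.54 in HFD 3 months, 0.50 in ND 4 days, 0.47 in HFD 4 days and 0.64 in aged (n = 3 each). Replicates are separate samples in the labels, and nothing there says that they are separate animals, so p-values measure the spread between these samples.

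The first comparison asks which genes differ in stem cells of mice fed a high fat diet for 3 months. Among the fixed gene groups, epidermal differentiation genes, which build the cornified layers of the epidermis, were higher in HFD than in ND 3 months telogen, with 24 of the 26 measured members above 0 and a median log2 difference of 0.41 (n = 3 arrays per group). Tgm1, a cross-linking enzyme of the cornified envelope, differed by 2.59 ± 0.93 (SE), the envelope protein Lor by 1.04 ± 0.74 and Casp14, a protease of late differentiation, by 2.27 ± 1.54. Camera gave an adjusted p of 0.00356 for this group over 39 lists, while the adjusted p = 0.807 with an estimated correlation. None of its 26 members passed the test, 0 over all genes and 0 adjusted over the list alone. The mean list score was 1.74 ± 0.51 (SD) in HFD and 1.08 ± 0.05 in ND, a difference of 0.66 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays can give). The scores were 1.17, 2.14 and 1.91 on HFD replicates 1 to 3 and 1.08, 1.04 and 1.13 on ND, so the difference lies in HFD replicates 2 and 3. Macrophage and Langerhans cell markers scored -1.66, -0.30 and -0.58 on the same HFD arrays and -1.26, -1.38 and -1.70 on ND, and that list did not pass (adjusted p 0.451). On the second principal component of the 20 arrays, HFD replicate 3 lay at 130.1 and the next highest array at 38.6. The call was lost without HFD 3 months telogen replicate 2 (median 0.21, adjusted p 0.373) and without replicate 3 (median 0.38, adjusted p 0.081). Scores of other lists that camera did not call also had no overlap between the groups, with the same permutation p. They were higher in HFD for interleukin-1 family (0.652), adipocyte (0.237) and unfolded protein genes (0.136). They were lower for BMP and TGF-beta (-0.362) and bulge stem cell genes (-0.175). Chance gives a share of 0.1 of lists without overlap. Interleukin-1 family genes, which carry inflammatory signals of keratinocytes, had a median of 0.37 with 12 of 16 members above 0 and did not pass (adjusted p 0.149). Its decoy receptor Il1r2 had a difference of 2.27 ± 0.64 and Il18 of 2.82 ± 1.13 (2 of 3 ND arrays well above background).

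Of the genes named for this question whatever their p, none passed between HFD and ND 3 months (limma, 3 arrays per group, adjusted p 1 for each). The bulge markers Cd34 and Lgr5 differed by -0.49 ± 0.27 and -0.58 ± 0.36 (log2, SE), Krt15 by -0.10 ± 0.30, Sox9 by 0.11 ± 0.36 and Col17a1, a hemidesmosome collagen that anchors these cells, by -0.07 ± 0.24. In the hedgehog pathway, which drives entry into anagen, Gli1 differed by 0.29 ± 0.61, Gli2 by -0.24 ± 0.62, Ptch1 by 0.22 ± 0.71 and Smo by -0.20 ± 0.48. Il1b differed by 0.10 ± 0.40 and its receptor Il1r1 by 0.29 ± 0.84. The suprabasal keratins Krt1 and Krt10 differed by 0.36 ± 0.64 and 0.27 ± 0.38 and the envelope precursor Ivl by 0.81 ± 1.23. For lipid storage and synthesis, Plin2 differed by -0.19 ± 0.47, Cd36 by -1.39 ± 1.83 (well above background on 2 of 3 arrays in each group) and Scd1 by 0.12 ± 0.44. The oxidative stress genes Nqo1 and Hmox1 differed by -0.43 ± 0.49 and -0.74 ± 0.58. Shh and Il1a were not tested, since their probes were well above background on 2 and 3 of the 20 arrays.

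No single gene passed the threshold between HFD and ND 3 months: limma called 0 of 18727 genes at an adjusted p below 0.05. At an unadjusted p below 0.05 there were 730, against 936 expected by chance, and the smallest adjusted p was 0.568. That value belonged to Apbb1, an adaptor protein, with -3.28 ± 0.51 (log2, SE; well above background on 2 of 3 HFD and 3 of 3 ND arrays). The next lower genes were Cd59b -2.83 ± 0.61, Zfp219 -4.47 ± 0.97 (2 of 3 HFD arrays), Nme3 -1.52 ± 0.34, and Apln, a secreted peptide that was at least 9.15-fold lower. On the other side stood Stx11 at 3.64 ± 0.67 (1 of 3 ND arrays), Nat9 at 2.23 ± 0.44, Fbxl18 at 2.79 ± 0.58, Ddx28 at 1.73 ± 0.36 and Pramel11, at least 3.92-fold higher. The count was 1 with quantile normalization, 1 with median scaling, 1 without ND 3 months telogen replicate 3 and 1 without HFD 3 months telogen replicate 3, and 0 under the other settings. In data simulated with 200 changed genes, the same fit recovered 0% of 2-fold, 27% of 4-fold and 59% of 8-fold changes, so 2-fold changes were not detectable with this number of arrays. Both groups lay on 1 slide, in different rows of it, so diet and row cannot be told apart.

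After 4 days on the high fat diet, no gene group and no gene passed. Camera called 0 of the 39 lists. Hmox1, which degrades heme under oxidative stress, differed by -1.24 ± 0.58 (log2, SE, n = 3 arrays per group) and Nqo1, a quinone reductase, by -0.97 ± 0.49; Il1r1 differed by 1.31 ± 0.84 and Il1b by 0.57 ± 0.40. Among bulge genes the differences were -0.16 ± 0.27 for Cd34, -0.38 ± 0.36 for Lgr5, -0.08 ± 0.30 for Krt15, -0.15 ± 0.36 for Sox9 and 0.15 ± 0.24 for Col17a1. Hedgehog genes gave 0.52 ± 0.61 for Gli1, 0.66 ± 0.62 for Gli2, 0.44 ± 0.71 for Ptch1 and 0.23 ± 0.48 for Smo. Krt1, Krt10 and Ivl gave 0.37 ± 0.64, -0.23 ± 0.38 and 1.42 ± 1.23, and Plin2, Cd36 and Scd1 gave -0.43 ± 0.47, -1.20 ± 1.83 (1 of 3 arrays in each group well above background) and -0.02 ± 0.44. Among the genes with the smallest adjusted p, 0.18, were Ccnj, a cyclin family gene, at 6.0 ± 0.86 (2 of 3 ND arrays well above background), and Crb2, at least 1.99-fold higher (1 of 3 HFD arrays, 0 of 3 ND). Others with a small p were Ppp1r3d (at least 13.7-fold higher), Asb3 2.91 ± 0.55 (2 of 3 ND arrays), Tmco2 3.30 ± 0.67, and on the lower side Tspan2 -3.35 ± 0.55, the clock repressor Bhlhe41 -3.63 ± 0.67, Mettl26 -2.73 ± 0.53 and Eya2 -1.85 ± 0.37. Limma called 0 of 18727 genes, and 817 lay at an unadjusted p below 0.05. The count was 1 when only the 6 arrays compared were fitted, 1 without ND 4 days telogen replicate 3 and 0 under the other settings. Simulated 2-fold, 4-fold and 8-fold changes were recovered in 0%, 26.5% and 65% of genes. Both groups lay on 1 slide, ND in row 1 and HFD in row 2, so diet and row cannot be told apart. The share of spots well above background was 77.09% to 83.49% on the ND arrays and 68.82% to 71.47% on the HFD arrays.

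The difference between the 3-month and the 4-day diet effects was tested directly, and neither a gene nor a list passed. Ddx28, an RNA helicase, had the positive departure with the smallest p, 3.13 ± 0.51 (log2, SE, 12 arrays), and among the next were Mob2 3.02 ± 0.64, Stx11 4.44 ± 0.95 and Mettl26 3.47 ± 0.75. On the negative side were Ptgdr2, a prostaglandin receptor, at -4.41 ± 0.72, Klf8 -7.58 ± 1.35, Ccnj -5.52 ± 1.21 and Tradd -2.95 ± 0.67. Ppp1r3d was also there, with a fitted -8.24 ± 1.55. That value rests on ND 4 days arrays on which the gene was not well above background, so its size was not measured. Limma called 0 genes (701 at an unadjusted p below 0.05, smallest adjusted p 0.426). The count was 1 with median scaling, 1 with only the 12 arrays fitted and 1 without ND 3 months telogen replicate 3. Simulated 8-fold differences were recovered in 38% of genes, and 4-fold ones in 0%.

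Ageing was compared first with ND 3 months, 24-month against 5-month mice. Basement membrane and adhesion genes, which fix the stem cells to their niche, were lower in aged telogen: 22 of 25 members lay below 0 with a median of -0.67 (n = 3 arrays per group, log2). Tnc, an extracellular matrix glycoprotein, fell by 3.56 ± 0.63 (SE) and Postn, a matricellular protein, by 0.88 ± 0.25 adjusted over the list alone, the 2 members that did; over all genes 0 of the 25 passed. Fn1, fibronectin, was at least 12.9-fold lower without passing, and Col17a1 differed by -0.67 ± 0.24, Lamb3 by -0.62 ± 0.24 and Itgb4 by -0.67 ± 0.28. The list score was 0.93 ± 0.27 (SD) in aged and 1.85 ± 0.21 in ND (exact two-sided permutation p = 0.1, the smallest possible). Camera gave an adjusted p of 1.81e-07 and 0.0256 with an estimated correlation, and 0.306 with slide as a block, where the median was -0.66. Bulge stem cell genes had a median of -0.35 (18 of 20 below 0; adjusted p 0.00417, and adjusted p = 0.504 with an estimated correlation) and Wnt signalling genes one of -0.44 (14 of 20; 0.00452, and adjusted p = 0.129 with an estimated correlation). Wnt10a, a ligand of follicle growth, differed by -2.15 ± 0.59 and Nkd1, a feedback inhibitor, was at least 3.69-fold lower, both without passing. For bulge and Wnt genes a slide block gave medians of -0.64 and -0.31 and adjusted p of 0.306 and 0.997. Of the fibroblast markers, Col6a1 fell by 1.69 ± 0.33 adjusted over its list alone, and that list did not pass (median -0.30, adjusted p 0.236).

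Single genes higher in aged than in ND 3 months telogen numbered 11 and lower ones 1 (limma, 18727 genes, n = 3 arrays per group). The vomeronasal receptor gene Vmn1r12 was at least 16.7-fold higher (adjusted p 6.12e-05), the limb transcription factor Tbx4 at least 11.6-fold (0.00426), Prl7d1, a placental prolactin family gene, at least 7.63-fold (0.00334) and the acute phase family gene Saa4 at least 11.7-fold (0.016). Bounds for Lce1i, a late cornified envelope gene, Alpl, tissue-nonspecific alkaline phosphatase, Akr1c12 and Hacd4 were 8.12, 8.4, 8.11 and 5.23. Mei1, a meiosis gene, rose by 3.01 ± 0.31 (log2, SE) and Ddx28 by 2.41 ± 0.36. Armcx1 fell by 3.42 ± 0.52 (0.0378). The remaining gene, Gm19531 with 1.65 ± 0.24, falls outside the naming rule and was chosen after its values were seen. Below the threshold on the lower side followed Lig4 -3.84 ± 0.67, Tnc, Poglut2 -2.48 ± 0.44, Plxna2 -1.97 ± 0.36 and Apbb1 -2.80 ± 0.51. A slide block gave 5 genes, 1 higher and 4 lower, none of them among the 12, as 0 of the 11 higher genes stayed called and Armcx1 turned to 0.17. The count was 6, 7 and 5 without ND 3 months telogen replicates 1, 2 and 3, 24 without aged replicate 2 and 7 without aged replicate 3. It was 2 with normexp, 20 with array weights, 0 when only the 6 arrays compared were fitted, and 0 among probes well above background on all 20 arrays, a filter that takes out dim probes like most of these, and 9 higher with 0 lower when the percentile came from those probes. Each aged array lay on a slide scanned apart from the ND slides. Simulated changes of 2, 4 and 8-fold were recovered in 0%, 21% and 65.5% of genes.

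The named genes of the diet question did not pass in ageing either (aged against ND 3 months, limma, smallest adjusted p 0.325 for Col17a1). Cd34 differed by -0.53 ± 0.27 (log2, SE, n = 3 arrays per group), Lgr5 by -0.65 ± 0.36, Krt15 by -0.19 ± 0.30 and Sox9 by -0.09 ± 0.36. Gli1, Gli2, Ptch1 and Smo gave -0.25 ± 0.61, -0.38 ± 0.62, 0.22 ± 0.71 and -0.53 ± 0.48. Il1b and Il1r1 gave 0.41 ± 0.40 and 0.77 ± 0.84, and Krt1, Krt10 and Ivl -0.67 ± 0.64, -0.58 ± 0.38 and -2.54 ± 1.23. Plin2, Cd36 and Scd1 gave -0.55 ± 0.47, -1.77 ± 1.83 and -0.39 ± 0.44, with Cd36 well above background on 1 of 3 aged and 2 of 3 ND arrays, and Nqo1 and Hmox1 -0.16 ± 0.49 and 0.55 ± 0.58.

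The second ageing comparison set aged telogen against the younger ND 4 days group, 24-month against 2-month mice. Here the basement membrane list was lower with a median of -0.48 (22 of 25 below 0, n = 3 arrays per group), and Tnc fell by 2.64 ± 0.63 (SE) adjusted over the list alone, the 1 member that did. Epidermal differentiation genes had a median of 0.54 (18 of 26 above 0), with the corneodesmosome gene Cdsn at 1.97 ± 0.62 and the protease gene Asprv1 at 2.01 ± 0.65. PPAR targets and fatty acid oxidation genes had a median of 0.59, with Angptl4, an inhibitor of lipoprotein lipase, at 1.79 ± 0.48. Camera called these 3 lists at adjusted p 0.00426, 0.00426 and 0.00665, and at adjusted p = 0.227, 0.686 and 0.227 with an estimated correlation. Wnt signalling (-0.57), bulge stem cell genes (-0.39), fibroblast markers (-0.57), immediate early genes (0.54) and red blood cell markers (0.76) were each called at 0.0335, the first 3 lower and the last 2 higher. They had adjusted p = 0.235, 0.66, 0.235, 0.66 and 0.408 with an estimated correlation. BMP and TGF-beta genes, which camera did not call, had scores without overlap (-0.412, exact two-sided permutation p = 0.1, the smallest possible). Adjusted over the list alone, Nkd1 fell at least 7.29-fold and the fibroblast collagen Col6a1 fell by 1.17 ± 0.33, and the globin genes Hba-a2 and Hbb-b2 rose by 1.44 ± 0.48 and 2.39 ± 0.85. With slide as a block the basement membrane median was -0.27 (adjusted p 0.319), the epidermal one 0.13 (0.263), the PPAR one 0.41 (0.147), the red blood cell one -1.09 (0.319), the bulge one -0.34 (0.319), the fibroblast one -0.18 (0.319) and the Wnt one -0.21 (0.848), and the immediate early list alone stayed called, at 1.0 (0.00954). Leaving out single arrays ended list calls, given with the median and adjusted p: without ND 4 days telogen replicate 1, the basement membrane (-0.33, 0.0519), immediate early (0.17, 0.0631), fibroblast (-0.70, 0.0915), red blood cell (0.89, 0.0857) and Wnt (-0.40, 0.115) lists were not called. Without ND 4 days telogen replicate 2, the bulge (-0.35, 0.234), epidermal (0.23, 0.136), immediate early (0.29, 0.0904), fibroblast (-0.54, 0.103), red blood cell (0.74, 0.0756) and Wnt (-0.55, 0.0904) lists were not called. Without ND 4 days telogen replicate 3, the bulge (-0.37, 0.0579), fibroblast (-0.49, 0.0609), red blood cell (0.95, 0.0579) and PPAR (0.37, 0.119) lists were not called. Without aged telogen replicate 1, the basement membrane (-0.41, 0.0765), bulge (-0.24, 0.219), epidermal (0.28, 0.219), immediate early (0.37, 0.319), fibroblast (-0.47, 0.219), red blood cell (0.74, 0.203), PPAR (0.36, 0.203) and Wnt (-0.62, 0.219) lists were not called. Without aged telogen replicate 2, the immediate early (0.41, 0.177) and PPAR (0.49, 0.0918) lists were not called. Without aged telogen replicate 3, the basement membrane (-0.60, 0.0781), bulge (-0.37, 0.119), fibroblast (-0.68, 0.0843), red blood cell (0.50, 0.246) and Wnt (-0.55, 0.119) lists were not called.

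In single genes, aged against ND 4 days gave 6 higher and 1 lower (limma, n = 3 arrays per group; 1470 at an unadjusted p below 0.05). Vmn1r12 was at least 19.2-fold higher (adjusted p 0.00068) and Prl7d1 at least 8.82-fold (0.00544). Mei1 rose by 2.98 ± 0.31 (log2, SE), Saa4 by 3.99 ± 0.51 and Tbx4 by 3.95 ± 0.57, the last 2 well above background on 1 of 3 ND arrays. The HFD 4 days anagen array, from 2-month mice, shares the row of the aged telogen arrays on slide 3. There Vmn1r12, Prl7d1, Mei1 and Saa4 lay at -2.41, -3.03, -0.94 and -2.58 (log2, 1 array). On the aged anagen array, in the other row, they lay at -7.16, -7.13, -4.56 and -6.74. Tbx4 lay at -7.64 and -7.15 on these 2 arrays. All 5 of these genes were also called against ND 3 months. Of the other genes called there, none passed here: Ddx28 differed by -0.33 ± 0.36 and so was not higher against this group, Lce1i by 1.64 ± 0.71, Akr1c12 by 2.95 ± 0.50 (2 of 3 ND arrays), Hacd4 by 2.39 ± 0.44 (1 of 3 ND arrays), Gm19531 by 1.47 ± 0.24 and Armcx1 by -2.41 ± 0.52, and Alpl was at least 9.72-fold higher. The other higher gene, Gm28154 with 2.59 ± 0.35, was chosen after its values were seen. Just below the threshold lay Zfp982 -4.05 ± 0.63 (1 of 3 aged arrays), Msx2, a hair matrix transcription factor, -1.62 ± 0.27, Dnase1 -1.78 ± 0.30, and the olfactory receptor genes Olfr922 and Olfr1270, at least 1.22-fold and 2-fold lower. Il1r1 differed by 2.09 ± 0.84 (adjusted p 0.565), Lgr5 by -0.76 ± 0.36, Cd34 by -0.55 ± 0.27, Col17a1 by -0.50 ± 0.24, Krt15 by -0.20 ± 0.30 and Sox9 by -0.24 ± 0.36. Gli1, Gli2, Ptch1 and Smo gave 0.67 ± 0.61, 0.84 ± 0.62, 0.15 ± 0.71 and -0.35 ± 0.48; Il1b, Krt1, Krt10 and Ivl gave -0.06 ± 0.40, 0.07 ± 0.64, -0.14 ± 0.38 and -0.68 ± 1.23. Plin2, Cd36 (1 of 3 arrays in each group), Scd1, Nqo1 and Hmox1 gave -0.42 ± 0.47, -0.56 ± 1.83, -0.52 ± 0.44, -0.99 ± 0.49 and 1.21 ± 0.58. A slide block gave a count of 1, a lower gene. The 7 calls became 4 without aged replicate 1, 3 with normexp, 0 when only the 6 arrays compared were fitted, 0 among probes well above background on all 20 arrays, 12 (8 higher, 4 lower) with quantile normalization and 9 (5 higher, 4 lower) with median scaling. Simulated 2, 4 and 8-fold changes were recovered in 0%, 35.5% and 64.5% of genes.

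The groups on the normal diet differ in age, in time on the diet and in slide, which cannot be told apart here. ND 3 months against ND 4 days telogen shows how far 2 control groups lie apart. Immediate early genes, which respond to stress and growth stimuli, were higher in ND 3 months with a median of 0.75, Fos at 3.93 ± 1.34 and Egr1 at 1.21 ± 0.53 (log2, SE, n = 3 arrays per group; adjusted p 0.000188, and adjusted p = 0.609 with an estimated correlation). Camera also called cell cycle (0.43), upper follicle (0.42), basement membrane (0.18) and epidermal differentiation genes (0.32) as higher. Their values were 0.017, 0.0399, 0.0399 and 0.0491, and adjusted p = 0.874, 0.749, 0.609 and 0.874 with an estimated correlation. Only the spindle gene Cenpf rose adjusted over the list alone, by 4.74 ± 1.12. Scores of 6 marker lists of other cell types, none called by camera, did not overlap between the groups (exact two-sided permutation p = 0.1 each, the smallest possible). They were lower for adipocyte (-0.62, 0 of 9 members above 0), Schwann cell (-0.88), smooth muscle (-0.43), mast cell (-0.37) and fibroblast markers (-0.34) and higher for red blood cell markers (0.40), where chance gives 10% of lists without overlap. Limma called 3 single genes, 1 higher and 2 lower in ND 3 months (adjusted p below 0.05). Of these, Ddx28 fell by 2.73 ± 0.36, and Gm28154, chosen after its values were seen, rose by 3.28 ± 0.35. Other genes near the threshold were Exog (at least 3.84-fold higher), Ppp1r3d (at least 20.3-fold higher), the death receptor adaptor Tradd at 2.79 ± 0.48, Ccnj at 5.02 ± 0.86 and Asb3 at 3.12 ± 0.55 (each of these 2 on 2 of 3 ND 4 days arrays). On the lower side were Samd8 -1.70 ± 0.25, Serpinb6e -1.94 ± 0.34, Zfp982 -3.89 ± 0.63 (2 of 3 ND 3 months arrays), Vmn1r202 and Olfr1276, the last 2 at least 1.71-fold and 1.58-fold lower. A slide block gave 7 genes (5 higher, 2 lower), and the cell cycle and epidermal medians were -0.80 (adjusted p 0.0253) and -0.36 (0.0185), called in the other direction. It also ended the immediate early (0.22, 0.885, with the direction of the test turned), basement membrane (0.24, 0.69) and upper follicle (0.21, 0.624) calls, given with the median and adjusted p. Leaving out single arrays ended list calls, given with the median and adjusted p: without ND 3 months telogen replicate 1, the cell cycle (0.35, 0.135), epidermal (0.22, 0.135) and upper follicle (0.28, 0.186) lists were not called. Without ND 3 months telogen replicate 2, the epidermal (0.35, 0.0641) list was not called. Without ND 3 months telogen replicate 3, the basement membrane (0.14, 0.298), cell cycle (0.11, 0.296), epidermal (0.37, 0.142) and upper follicle (0.37, 0.142) lists were not called. Without ND 4 days telogen replicate 1, the epidermal (0.24, 0.0526) list was not called. Without ND 4 days telogen replicate 2, the basement membrane (0.19, 0.152), cell cycle (0.10, 0.399), epidermal (0.12, 0.544) and upper follicle (0.27, 0.153) lists were not called. Without ND 4 days telogen replicate 3, the basement membrane (0.22, 0.27), cell cycle (0.49, 0.107) and upper follicle (0.39, 0.208) lists were not called. The count of 3 was 1 and 0 without ND 3 months telogen replicates 1 and 2, and 0 without ND 4 days telogen replicate 1, and 0 when only the 6 arrays compared were fitted; with the percentile over probes detected on all arrays it was 2 higher and 1 lower. Simulated 2, 4 and 8-fold changes were recovered in 0%, 25.5% and 65% of genes.

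**Figure D1:**
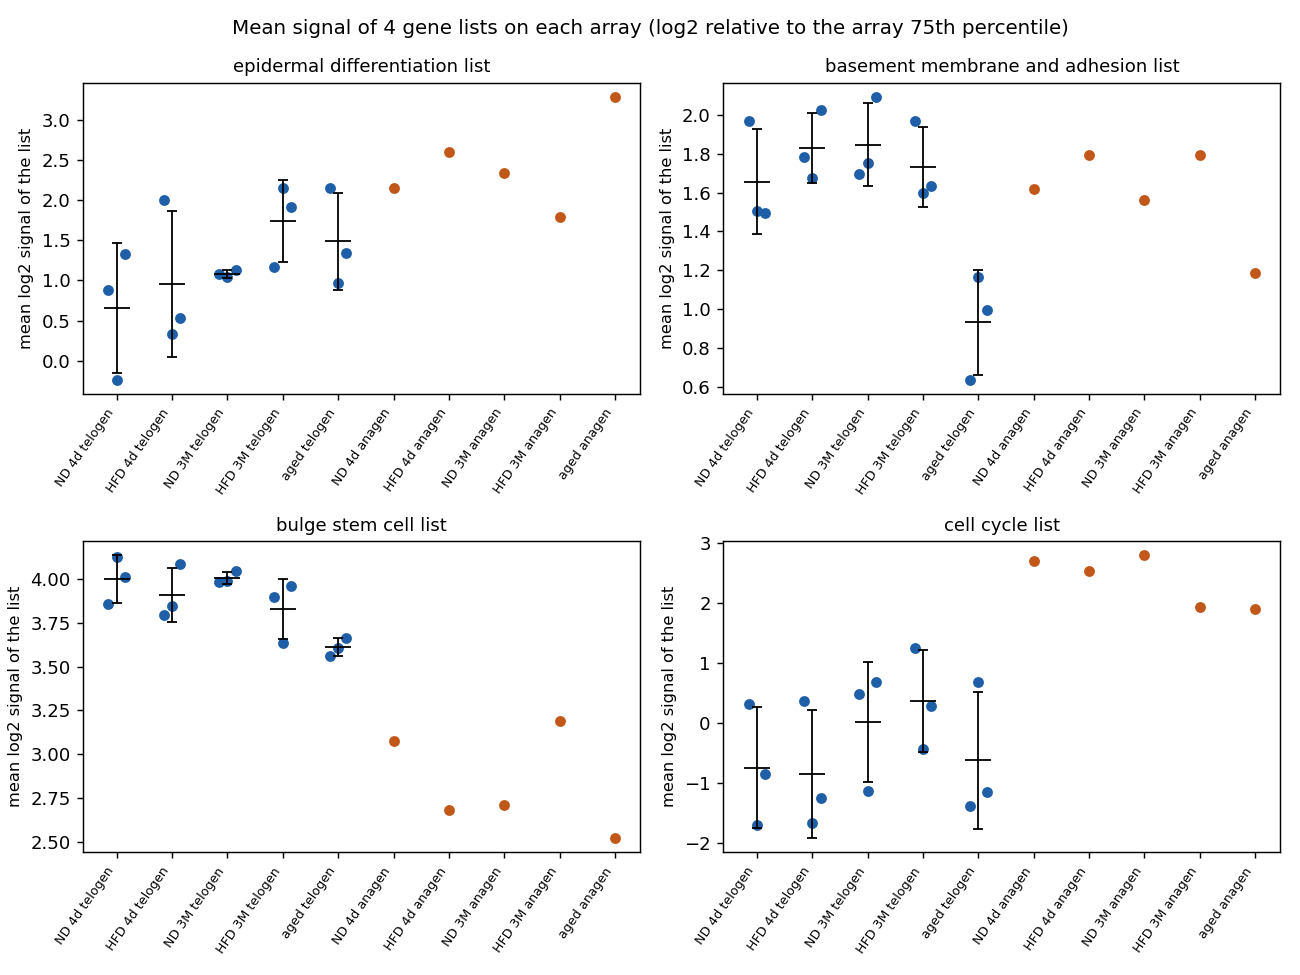
Mean log2 level of the members of 4 gene lists on each array (y axis, log2 signal relative to the 75th percentile of the array) by condition (x axis). Points are arrays, blue for telogen and orange for anagen, and lines with bars give the telogen mean ± SD (n = 3); the basement membrane scores of the aged telogen arrays average 0.93 against 1.85 in ND 3 months.

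Since the series title speaks of a converging mechanism, calls of the diet and the ageing comparisons were set side by side. No gene was called in both HFD 3 months and ageing, as limma called 0 genes in the diet comparison; with quantile normalization or median scaling the overlap was 1 gene. At an unadjusted p below 0.05, 90 genes were higher and 79 lower both in HFD 3 months and in aged, against the same ND 3 months arrays, where independent lists would share 26.5 and 15.7. The differences of the 2 comparisons correlated across genes, which are not independent replicates, at r = 0.381 (rho 0.333), and unchanged groups simulated against those shared controls gave r = 0.5. The covariance was 0.266 against 0.278 in the simulation. For pairs with shared arrays the simulated covariance was 0.278 or 0.279, whichever group was shared. The median standard deviation of a gene within a group ran from 0.43 in ND 3 months to 0.64 in aged. The simulation thus took no account of unequal spread. It cannot tell whether these pairs share more or less than unchanged groups would. With ND 4 days as the control of ageing, so that no array is shared, r was 0.033 (rho 0.034) and the covariance 0.022 against 0.001. There 23 genes were higher and 44 lower in both, against 9.77 and 19.5 for independent lists. All these comparisons come from 1 fit that shares the estimate of each gene's spread. Their lists are therefore not independent even without shared arrays, and an excess over these expected counts cannot be read as shared genes. HFD 3 months and HFD 4 days gave r = -0.002 (rho 0.023). At an unadjusted p below 0.05, 11 genes were higher and 25 lower in both, against 7.24 and 8.69 for independent lists. HFD 4 days and aged, both against ND 4 days, gave r = 0.481 with 0.5 simulated, and a covariance of 0.339 against 0.279. With ND 3 months as the control of ageing, HFD 4 days and aged gave r = -0.056 (rho -0.035) and a covariance of -0.041 against -0.002, and 24 genes were higher and 26 lower in both, against 32.3 and 16.3. The 2 ageing comparisons, which share the aged arrays, gave r = 0.502 with 0.499 simulated, and a covariance of 0.404 against 0.278. Limma called 5 genes higher in both, against 0.00352 for independent lists, which take no account of the shared arrays. At an unadjusted p below 0.05, 210 genes were higher and 281 lower in both, against 43.5 and 36.6.

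Anagen arrays were compared with telogen arrays across the 5 conditions, to see what separates growing from resting follicle stem cells. All anagen arrays lay in column 1 of a slide and all telogen arrays in columns 2 to 4, so phase and column cannot be told apart. Cell cycle genes rose: 25 of 29 measured members passed over all genes and 29 adjusted over the list alone, with a median log2 difference of 2.86 (5 anagen and 15 telogen arrays). The mitotic checkpoint kinase gene Bub1 rose by 4.90 ± 0.88 (SE; well above background on 4 of 15 telogen arrays), cyclin Ccnb2 by 3.10 ± 0.51, the replication helicase subunit Mcm5 by 2.41 ± 0.43 and Cdc20 by 1.93 ± 0.25. Bulge stem cell genes fell: 9 of 20 passed, all lower, and 12 adjusted over the list alone, with a median of -0.53. Cd34 fell by 2.19 ± 0.20, Id2, an inhibitor of differentiation induced by BMP, by 2.40 ± 0.23, Fgf18, which holds follicles in telogen, by 4.78 ± 0.64, and Dkk3 by 1.20 ± 0.16. Camera gave adjusted p of 5.8e-28 and 1.65e-06, and adjusted p = 0.0511 for each with an estimated correlation, under which none of the 12 called lists passed.

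Among the other groups, BMP and TGF-beta genes were lower (-0.85, adjusted p 0.0145, 7 fell and 2 rose), with Id3 at -1.88 ± 0.23 and the antagonist Grem1 at -1.10 ± 0.15 (5 anagen and 15 telogen arrays). Circadian clock genes were lower (-0.88, 2.11e-05, 6 of 16 fell), including the repressor genes Cry2 -1.61 ± 0.20 and Per1 -1.44 ± 0.24 and the output factor Tef -1.11 ± 0.15. Epidermal differentiation genes were higher (0.83, 1.65e-06, 8 rose and 1 fell), led by Sprr1b 5.48 ± 1.09 and Sprr2h 3.98 ± 0.83 (9 of 15 telogen arrays), small proline-rich proteins, with Klf4, a barrier transcription factor, at -0.78 ± 0.15. Interleukin-1 family genes were higher (0.69, 0.0077, 3 rose), among them Il1b 1.00 ± 0.28 and Il1f8 3.84 ± 1.06 (4 of 5 anagen and 4 of 15 telogen arrays). Cholesterol synthesis genes (0.61, 2.52e-05, 3 rose) included Sqle 1.99 ± 0.49 and Idi1 0.83 ± 0.22. Oxidative phosphorylation (0.15, 1 rose, Cox5a 0.88 ± 0.17), sebaceous (0.39, 1 rose, Prdm1 2.74 ± 0.65) and upper follicle genes (0.53, 3 rose and 1 fell, Lrig1 1.18 ± 0.23 and Krt79 1.45 ± 0.27) were higher at 0.0077, 0.0144 and 0.0407. Ribosomal protein genes (-0.28, 1 fell, Rps24 -1.31 ± 0.20) and red blood cell markers (-1.11, 1 fell, Hba-a2 -1.24 ± 0.36) were lower at 0.0212 and 0.0407. With an estimated correlation these lists gave adjusted p = 0.0527 for BMP and TGF-beta, 0.0511 for the clock and interleukin-1 lists, 0.309 for cholesterol, 0.671 for the ribosome and 0.323 for the others. A slide block ended the BMP and TGF-beta (-0.60, 0.124) call, and so did the 3 conditions whose phases share a slide (-0.60, 0.171), given with the median and adjusted p. Quantile normalization ended the ribosome (-0.08, 0.347) and upper follicle (0.57, 0.0808) calls and median scaling the ribosome (-0.06, 0.225) and upper follicle (0.74, 0.0646) calls. Among probes well above background on all 20 arrays the IL-1 family and receptors (0.20, 0.543), red blood cell (-1.26, 0.126) and upper follicle (0.53, 0.0666) lists were not called. Normexp ended the red blood cell (-0.62, 0.064) call and ranks the BMP and TGF-beta (-0.85, 0.0944) and upper follicle (0.53, 0.11) calls. Leaving out single arrays ended list calls, given with the median and adjusted p: without the HFD 3 months anagen array, the BMP and TGF-beta (-0.84, 0.0571), red blood cell (-1.23, 0.0571) and upper follicle (0.56, 0.0571) lists were not called. Without the ND 3 months anagen array, the ribosome (-0.23, 0.0678), red blood cell (-0.76, 0.0915) and upper follicle (0.59, 0.0678) lists were not called. Without the ND 4 days anagen array, the ribosome (-0.23, 0.128), red blood cell (-0.98, 0.0655), sebaceous (0.24, 0.0655) and upper follicle (0.52, 0.0513) lists were not called. Without the aged anagen array, the red blood cell (-0.95, 0.123) and upper follicle (0.50, 0.0812) lists were not called. Of these genes, Il1f8, Il1b, Sqle and Prdm1 did not pass with slide as a block.

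Lists that camera did not call still held changed members (anagen against telogen, 5 and 15 arrays). In the hedgehog list, the target genes Gli1 and Ptch1 rose by 1.52 ± 0.37 and 1.47 ± 0.41 (log2, SE), and the coreceptors Boc and Cdon fell by 1.60 ± 0.26 and 2.22 ± 0.47 (list median 0.14, adjusted p 0.377). Hemidesmosome and basement membrane genes Lamb3, Itgb4, Egfl6 and Col17a1 fell by 1.30 ± 0.19, 1.07 ± 0.19, 1.13 ± 0.21 and 0.72 ± 0.16 (2 of 25 rose and 5 fell; list median -0.04, adjusted p 0.56). Fibroblast markers Col6a2, Col1a2, Col6a1 and Sparc fell by 2.23 ± 0.37, 1.90 ± 0.32, 1.44 ± 0.22 and 1.03 ± 0.18 (1 of 12 rose and 4 fell; list median -0.32, adjusted p 0.3). Duox1, a source of hydrogen peroxide, fell by 2.47 ± 0.24, the Wnt inhibitor Wif1 by 1.96 ± 0.41 and the antioxidant metallothionein Mt1 by 1.18 ± 0.24. Txnrd1 and Gpx2, antioxidant enzymes, rose by 1.82 ± 0.41 and 1.66 ± 0.43. Rises were also found for the fatty acid binding protein Fabp5 with 1.67 ± 0.29, the desaturase Scd2 with 2.46 ± 0.59, Elovl6 with 1.43 ± 0.39, the uncoupling protein Ucp2 with 1.32 ± 0.37 and the immediate early genes Egr1 and Egr2 with 1.18 ± 0.31 and 1.89 ± 0.43. Interferon-induced Ifi27l2a and Oas1a rose by 2.39 ± 0.41 and 2.45 ± 0.54 (the latter on 12 of 15 telogen arrays), and Usp18 fell by 2.30 ± 0.47 (3 of 5 anagen arrays). The inner root sheath keratin Krt28 rose by 1.37 ± 0.34, the companion layer keratin Krt75 fell by 2.56 ± 0.50 (3 of 5 anagen arrays), and Mitf, a melanocyte factor, fell by 2.34 ± 0.54. S100a8, an alarmin, rose by 5.12 ± 0.93 (1 of 15 telogen arrays) and the NF-kappaB inhibitor Nfkbia fell by 1.08 ± 0.26. Laptm5, a leukocyte marker, rose by 2.13 ± 0.61 (4 of 5 anagen and 11 of 15 telogen arrays). A slide block ended the calls of Nfkbia, Ucp2, Wif1, Scd2, Elovl6, Krt75, Cdon, Ptch1, Egr1, Oas1a, Laptm5, Mt1, Txnrd1 and Gpx2.

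Over all genes, limma called 1145 of 18727 in anagen against telogen (adjusted p below 0.05; 526 higher, 619 lower; 915 at least 2-fold). The largest rises were those of Pcp4 6.82 ± 1.42 (log2, SE; well above background on 6 of 15 telogen arrays), the gasdermin gene Gsdmc3 6.20 ± 1.62 (6 of 15), Krt6b, a keratin of activated keratinocytes and the companion layer, 6.06 ± 0.98, the stefin gene Stfa1 5.80 ± 1.16 (13 of 15) and Cstdc6 5.69 ± 0.74 (13 of 15). They were followed by Sprr1b, the origin recognition gene Orc1 5.22 ± 1.05 (7 of 15), the spindle gene Aspm 5.21 ± 1.18 (7 of 15), Eda2r 5.13 ± 0.75 (6 of 15) and Ulbp1, a stress ligand, at least 12.2-fold. The neuropeptide gene Cck was at least 57.6-fold lower, St6galnac5, Grik1 and Zfp78 at least 13.5-fold, 9.81-fold and 6.18-fold. The Wnt receptor Fzd9 fell by 5.84 ± 0.78 (1 of 5 anagen arrays well above background), the cell cycle inhibitor Cdkn1c by 5.83 ± 0.86 (1 of 5), Angptl7 by 5.31 ± 0.92 (4 of 5), Kif5c by 5.23 ± 0.96 (2 of 5), Sncg by 5.09 ± 0.51 and Igf2bp3 by 4.91 ± 0.77 (3 of 5). With median scaling the split was 653 higher and 336 lower; all genes had a median difference of -0.16 with the 75th percentile and 0.06 with the median, and of -0.14 and 0.00 in ND 3 months against ND 4 days. The count was 555 without the ND 3 months anagen array, 2056 without HFD 3 months, 609 without ND 4 days, 563 without HFD 4 days and 761 without the aged one. It was 677 (207 higher, 470 lower; 514 among the 1145) with slide as a block. It was 317 (111 higher, 206 lower; 256 among the 1145) in the 3 conditions whose phases share a slide, an alternative added after seeing the data. Simulated 2, 4 and 8-fold changes were recovered in 7%, 79% and 92.5% of genes. With a slide block Pcp4, Gsdmc3, Aspm and Grik1 no longer passed.

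**Figure D2:**
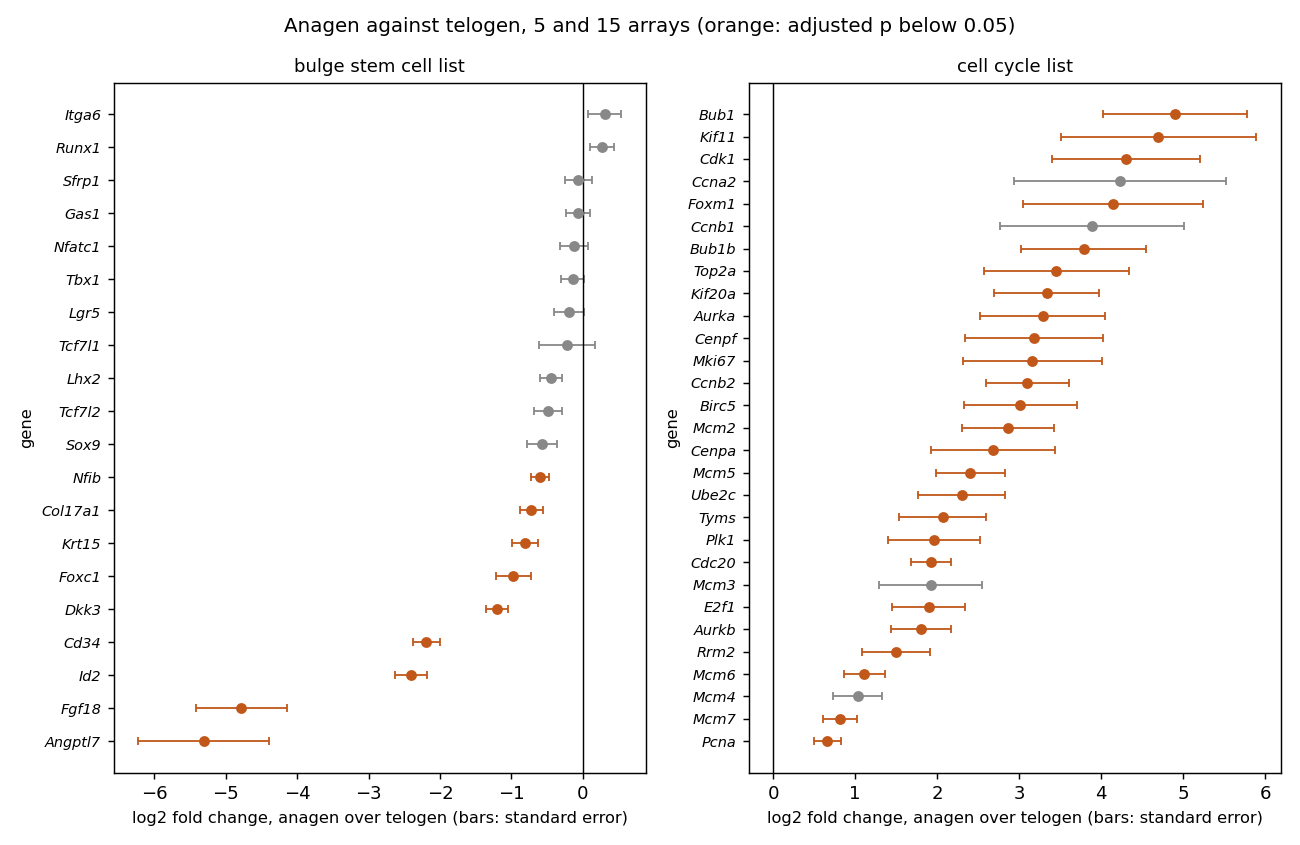
Log2 difference between anagen and telogen (x axis, ± SE from limma) for each measured member of the bulge stem cell and cell cycle lists (y axis), over 5 anagen and 15 telogen arrays. Orange points passed an adjusted p of 0.05, 9 of 20 bulge genes and 25 of 29 cell cycle genes.

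Diet and age differences within anagen rest on 1 array per condition, so they carry no error and no test and describe those arrays alone. In HFD 3 months against ND 3 months anagen, hedgehog genes had a median log2 difference of -0.90 (2 of 15 higher; percentile 0 among 10000 random lists of like expression), with Gli1 at -1.32, Gli2 at -1.41, Ptch1 at -1.21 and Smo at -1.36. Cell cycle genes had -0.81 (0 of 29 higher; percentile 0), NF-kappaB targets 1.21 (percentile 97.8) and macrophage and Langerhans cell markers 1.40 (99.6). The interleukin-1 family list had -0.08 (7 of 16 higher; percentile 3.3), with Il1b at 2.06 and Il1r1 at 2.44. On the first principal component of the 20 arrays, this pair held the extremes of anagen, ND at -125.9 and HFD at -42.8. Telogen arrays lay from -28.9 to 89.4, so HFD 3 months was the anagen array nearest to telogen. An effect of the diet and an array less like anagen cannot be told apart here. The same ND 3 months array is the control of an aged pair. Aged against ND 3 months anagen gave -0.71 for hedgehog (0.2), -0.83 for cell cycle (0), 0.92 for epidermal differentiation (100), 1.54 for NF-kappaB targets (100) and 2.51 for macrophage markers (100). Against ND 4 days, aged anagen gave -0.38 for hedgehog (3), -0.63 for cell cycle (0.1), 1.18 for PPAR targets (100), 2.17 for macrophage markers (100), 1.55 for immediate early genes (100), 1.24 for NF-kappaB targets (100) and 0.81 for epidermal differentiation (100). HFD 4 days against ND 4 days anagen gave -0.27 for hedgehog (9.6), -0.17 for cell cycle (20.2), 0.37 for epidermal differentiation (99.9) and -0.71 for NF-kappaB targets (0.3). Other lists at a percentile of at most 1 or at least 99 were cholesterol synthesis -0.45 (0.5), ribosome 0.57 (99.7) and immediate early -0.48 (0.1) in HFD 3 months and immediate early 0.61 (100), red blood cell 1.58 (99.8) and PPAR 0.55 (99.9) in HFD 4 days. For aged they were PPAR 0.67 (99.7) against ND 3 months and bulge -0.18 (0.6), fatty acid synthesis -0.70 (0.2), interleukin-1 0.73 (99.8) and interferon response -0.63 (0.5) against ND 4 days. In each of these 4 pairs the arrays lay on different slides, and the share of spots well above background was 60.7% on the ND 3 months array, 70.26% on HFD 3 months, 71.11% on ND 4 days, 69.97% on HFD 4 days and 64.89% on aged.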

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

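The tests of genes of the aged group on the anagen array that shares their row, of the slide term on these genes, of the share of bulge cells and of splits at an unadjusted p were chosen only after the result was seen, and the criteria of the first and the third were made stricter afterwards. Probes without a gene name, which the gene comparisons do not use, also passed the threshold: 1 in HFD against ND 3 months, 7 in aged against ND 3 months, 4 in aged against ND 4 days, 28 in ND 3 months against ND 4 days, 1 in diet by duration and 270 in anagen against telogen, of 16537 tested.

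Genes higher and basement membrane genes lower in aged than in ND 3 months telogen form the first pattern, and the aged arrays share slide 3. With slide as a term the 11 higher genes had a median fitted difference of -0.30 in place of 3.90. Most of these genes are known only as lower bounds, so the fitted 3.90 is not a measured size. The median standard error rose from 0.50 to 2.05, so slide and age cannot be told apart for them. On the HFD 4 days anagen array, in the same row, 5 of the 11 lay above every array off slide 3, against 3 on the highest other anagen array (one-sided Fisher exact p = 0.33), and over all genes the number was 14 against 12, which leaves a signal shared along the row open. For basement membrane genes the median with slide as a term was -0.66 (camera p 0.102), which also leaves the slide open. Fewer stromal cells as the whole cause is argued against by the keratinocyte part of the list, with a median of -0.60 (16 genes, camera p 8.41e-06) beside -0.88 for the stromal part, and age itself stays open.

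Epidermal differentiation genes higher in HFD than in ND 3 months telogen form the second pattern. Background subtraction as the whole cause is argued against by the 17 members brighter than the 75th percentile, whose median was 0.36. The dimmer members had a median of 0.65, so a part of background in the difference stays open. Variation between arrays in the share of differentiated epidermal cells may account for the pattern: the difference of the list scores was 1.24 standard errors of the pooled spread (0.66 with an SD of 0.65). An effect of the diet stays open beside it.

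Genes differing between anagen and telogen form the third pattern. Of the called genes, 100% had the same direction in the 3 conditions whose phases share a slide, which is partly built in since these conditions contribute to the calls; fitted alone, those conditions called 317 genes, so slide is argued against as the whole cause. Dim probes as the whole cause are argued against by the 1005 genes called among probes well above background on all 20 arrays. The share of called genes was 8.91% of genes brighter than the 75th percentile and 4.24% of the others. These shares may also reflect how precisely bright and dim genes are measured, so they do not exclude a part from dim probes. A lower share of bulge cells among the cells collected stays open: 3 of 12 marker lists of other cell types had a median above 0, and 0 were lower after adjustment over the 12 lists. None of these lists covers other follicle or epidermal keratinocytes, so they cannot decide this. Epidermal differentiation (0.83), upper follicle (0.53) and sebaceous genes (0.39) were called higher in anagen and bulge genes lower (-0.53). The hair lineage list was not called. An effect of the hair cycle phase itself may also account for the pattern and was not separated from the share of bulge cells. Nor was it separated from the column of the slide, since all anagen arrays lay in a column without telogen arrays. A slide term does not remove a column effect.

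For anagen against telogen, chance is argued against: 1 of 100 splits of the arrays gave as many genes, the real one with 1145, and the highest other gave 128. These splits do not separate phase from the column of the slide. For diet by duration the real count is 0, which 100 of 100 splits reach by construction (highest other 2), so this count says nothing about chance. At an unadjusted p below 0.05, 61 of 100 splits gave at least its 701 genes (highest other 964), so there chance cannot be excluded. In comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. The real count and the highest other were 0 and 3 for HFD 3 months, 0 and 1 for HFD 4 days, 12 and 1 for aged against ND 3 months, 7 and 3 for aged against ND 4 days, and 3 and 1 for ND 3 months against ND 4 days. The splits with at least the real count numbered 10, 10, 1, 1 and 1 in this order, the first 2 by construction since their real count is 0. At an unadjusted p below 0.05 the real count and the highest other were 730 and 853, 817 and 970, 2232 and 1257, 1470 and 2432, and 2219 and 891 in this order, and 4281 and 4181 for anagen against telogen.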

How the results depend on the processing

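The alternatives with the conditions whose phases share a slide and without genes also high on the HFD 4 days anagen array were chosen only after the result was seen. Of the counts of genes past the threshold, 116 stayed within 1.5 times under the alternatives and 47 moved. Of the gene values 3975 kept direction and side of the threshold, 311 lost the call, 17 gained one and 101 turned. Lists kept both in 480 cases, lost the call in 145, and camera's direction turned in 5, in 3 of them with the median. In anagen against telogen none of 1501 gene values turned and 210 lost the call. Signal over background limits the aged comparisons, whose counts were 0 among probes well above background on all 20 arrays; 64.32% to 83.49% of the spots of a telogen array were well above background. A group left with 2 telogen arrays shares the spread of all groups, and without its anagen array a condition does not enter the anagen difference. Median scaling moved the median log2 difference of all genes from -0.05 to -0.19 in HFD 4 days, from 0.06 to -0.22 in aged against ND 3 months and from -0.09 to -0.22 in aged against ND 4 days. Replicate numbers do not pair the samples: 30 pairs of arrays with the same number had a median r of 0.013 and 60 with different numbers 0. The cause was not tested for any of the values that follow.

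With normexp on the median signal, the counts were 2 in aged against ND 3 months and 3 in aged against ND 4 days. The direction turned there for Il1b 0.06 (aged against ND 4 days). With quantile normalization, the counts were 1 in HFD 3 months, 12 in aged against ND 4 days and 1 for genes in both HFD 3 months and ageing. The direction turned there for Scd1 0.05 (HFD 4 days). With median scaling, the counts were 1 in HFD 3 months, 1 in diet by duration and 1 for genes in both HFD 3 months and ageing. The direction turned there for Ptch1 -0.06 (aged against ND 3 months), Krt1 -0.06 (aged against ND 4 days). With percentile over probes detected on all arrays, the direction turned for Krt15 0.00, Scd1 0.07 (HFD 4 days), Sox9 0.00 (aged against ND 3 months), Il1b 0.05 (aged against ND 4 days). With probes well above background on all 20 arrays, the counts were 0 in aged against ND 3 months and 0 in aged against ND 4 days. With mean of the probes of a gene, the direction turned for Plin2 0.23, Sox9 -0.06 (HFD 3 months), Ptch1 -0.64 (HFD 4 days), Plin2 0.65 (aged against ND 3 months), Plin2 0.37 (aged against ND 4 days). With array weights, the counts were 20 in aged against ND 3 months, 5 in ND 3 months against ND 4 days and 1761 in anagen against telogen. The direction turned there for Ptch1 -0.11 (HFD 3 months), Scd1 0.03 (HFD 4 days), Ptch1 -0.29 (aged against ND 3 months), Ptch1 -0.41, Krt1 -0.03, Ivl 0.09 (aged against ND 4 days). With an estimated correlation, the list calls left were 0 of 1 in HFD 3 months, 1 of 3 in aged against ND 3 months, 0 of 8 in aged against ND 4 days, 0 of 5 in ND 3 months against ND 4 days and 0 of 12 in anagen against telogen. Among the lists not called there the medians were 0.41 for epidermal differentiation genes in HFD 3 months and -0.48 for basement membrane and adhesion genes in aged against ND 4 days. With an adjusted p below 0.01, the counts were 4 in aged against ND 3 months, 3 in aged against ND 4 days, 0 in ND 3 months against ND 4 days and 407 in anagen against telogen. With only the groups compared, the counts were 1 in HFD 4 days, 0 in aged against ND 3 months, 0 in aged against ND 4 days, 0 in ND 3 months against ND 4 days and 1 in diet by duration. With replicate number as a block (replicate block), the counts were 7 in aged against ND 3 months and 0 in ND 3 months against ND 4 days. With slide as a block, the counts were 5 in aged against ND 3 months, 1 in aged against ND 4 days, 7 in ND 3 months against ND 4 days and 677 in anagen against telogen. For aged against ND 3 months, slide block values of genes named by the rule turned for Vmn1r12 -4.97, Prl7d1 -2.46, Saa4 -5.58, Hacd4 -0.30, Mei1 -4.29, Armcx1 0.17, Plxna2 2.06, Gli1 1.57, Gli2 0.42, Smo 1.35, Il1b -1.63, Cd36 0.92, Ivl 0.05, Hmox1 -0.57, Scd1 1.12. The call of such genes ended, without a turn, for Tbx4 0.39, Lce1i 3.47, Alpl 3.31, Akr1c12 0.76, Ddx28 0.24 in aged against ND 3 months. Lists that lost their call with the slide block were basement membrane and adhesion -0.66, bulge stem cell -0.64, Wnt signalling -0.31 in aged against ND 3 months. For aged against ND 4 days, slide block values of genes named by the rule turned for Prl7d1 -1.53, Vmn1r12 -3.33, Saa4 -3.40, Mei1 -2.66, Ptch1 -0.09, Smo 0.05, Hmox1 -1.27. The call of such genes ended, without a turn, for Tbx4 1.5 in aged against ND 4 days. Camera's direction turned with the slide block for the lists fibroblast -0.18, red blood cell -1.09 in aged against ND 4 days. Lists that lost their call with the slide block were basement membrane and adhesion -0.27, bulge stem cell -0.34, epidermal differentiation 0.13, PPAR targets and fatty acid oxidation 0.41, Wnt signalling -0.21 in aged against ND 4 days. For ND 3 months against ND 4 days, slide block values of genes named by the rule turned for Exog -0.20, Asb3 -0.78, Samd8 0.13, Serpinb6e 0.40. The call of such genes ended, without a turn, for Ddx28 -0.88 in ND 3 months against ND 4 days. Camera's direction turned with the slide block for the lists cell cycle -0.80, epidermal differentiation -0.36, immediate early genes 0.22 in ND 3 months against ND 4 days. Lists that lost their call with the slide block were basement membrane and adhesion 0.24, upper follicle (isthmus and infundibulum) 0.21 in ND 3 months against ND 4 days. In anagen against telogen, the slide block ended calls that included Pcp4, Gsdmc3, Aspm, Grik1, Il1f8, Il1b, Nfkbia, Ucp2, Wif1, Sqle, Scd2, Elovl6, Krt75, Cdon, Ptch1, Egr1, Oas1a, Laptm5, Mt1, Txnrd1, Gpx2 and Prdm1. Lists that lost their call with the slide block were BMP and TGF-beta signalling -0.60 in anagen against telogen. Outside the rule, Gm19531 turned to -1.08 in aged against ND 3 months. In the conditions with both phases on one slide, the count was 317 in anagen against telogen. Without genes also high on the HFD 4 days anagen array, the counts were 7 in aged against ND 3 months and 3 in aged against ND 4 days. Across fits without 1 array, HFD 3 months gave the count from 0 to 1, Gli2 from -0.52 to 0.17, Ptch1 from -0.38 to 0.60, Smo from -0.43 to 0.11, Il1b from -0.15 to 0.41, Il1r1 from -0.38 to 1.07, Cd36 from -3.02 to 0.22, Sox9 from -0.05 to 0.28, Col17a1 from -0.13 to 0.00, Scd1 from -0.07 to 0.45, epidermal differentiation from 0.21 to 0.54. Across fits without 1 array, HFD 4 days gave the count from 0 to 1, Gli1 from -0.06 to 1.07, Ptch1 from -0.09 to 0.76, Smo from -0.15 to 0.60, Cd36 from -2.11 to 0.59, Krt1 from -0.16 to 0.89, Krt10 from -0.57 to 0.04, Krt15 from -0.26 to 0.01, Sox9 from -0.37 to 0.11, Scd1 from -0.26 to 0.23. Across fits without 1 array, aged against ND 3 months gave the count from 5 to 24, Gli1 from -0.85 to 0.17, Gli2 from -0.94 to 0.18, Ptch1 from -0.18 to 0.88, Krt15 from -0.52 to 0.05, Sox9 from -0.43 to 0.17, Nqo1 from -0.47 to 0.11. Across fits without 1 array, aged against ND 4 days gave the count from 4 to 6, Ptch1 from -0.38 to 0.81, Smo from -0.65 to 0.02, Il1b from -0.43 to 0.20, Plin2 from -0.91 to 0.03, Cd36 from -1.75 to 1.23, Krt1 from -0.38 to 0.69, Krt10 from -0.42 to 0.13, Ivl from -1.77 to 0.56, Krt15 from -0.54 to 0.03, Sox9 from -0.59 to 0.02, basement membrane and adhesion from -0.69 to -0.33. The count in fits without 1 array went from 0 to 4 in ND 3 months against ND 4 days, from 0 to 1 in diet by duration and from 555 to 2056 in anagen against telogen.

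In telogen, list calls ended under other settings too. Normexp ended the calls of the lists epidermal (0.28, 0.0764) and upper follicle (0.34, 0.0764) in ND 3 months against ND 4 days, each with its median and adjusted p. Quantile normalization ended the calls of the lists bulge (-0.23, 0.0563) in aged against ND 3 months, and bulge (-0.24, 0.224), fibroblast (-0.51, 0.0557), red blood cell (0.78, 0.0557) and Wnt (-0.60, 0.0557) in aged against ND 4 days, and basement membrane (0.17, 0.0699), cell cycle (0.47, 0.0668), epidermal (0.35, 0.0835) and upper follicle (0.40, 0.0699) in ND 3 months against ND 4 days. Median scaling ended the calls of the lists bulge (-0.52, 0.06) and fibroblast (-0.70, 0.06) in aged against ND 4 days. The percentile over probes detected on all arrays ended the calls of the lists bulge (-0.28, 0.0795) and red blood cell (0.88, 0.0558) in aged against ND 4 days, and epidermal (0.35, 0.0546) in ND 3 months against ND 4 days. Leaving out the filter on dim probes ended the calls of the lists immediate early (0.52, 0.0542) and Wnt (-0.53, 0.0528) in aged against ND 4 days. The filter on probes well above background on all 20 arrays ended the calls of the lists bulge (-0.31, 0.0514) in aged against ND 4 days, and basement membrane (0.19, 0.0552), cell cycle (0.37, 0.159), epidermal (0.31, 0.191) and upper follicle (0.42, 0.0964) in ND 3 months against ND 4 days. The mean of the probes of a gene ended the calls of the lists upper follicle (0.42, 0.0515) in ND 3 months against ND 4 days. The series table ended the calls of the lists epidermal (0.33, 0.0502) in ND 3 months against ND 4 days. Ranks ended the calls of the lists immediate early (0.54, 0.0628) and red blood cell (0.76, 0.158) in aged against ND 4 days, and upper follicle (0.42, 0.0545) in ND 3 months against ND 4 days. Fitting only the groups compared ended the calls of the lists bulge (-0.39, 0.112) and red blood cell (0.76, 0.0731) in aged against ND 4 days, and basement membrane (0.18, 0.0652), epidermal (0.32, 0.115) and upper follicle (0.42, 0.0652) in ND 3 months against ND 4 days. A replicate block ended the calls of the lists basement membrane (0.18, 0.056) and epidermal (0.32, 0.057) in ND 3 months against ND 4 days.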

Other observations

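The families of gene symbols below and the test of arrays on 1 slide were chosen only after the result was seen. Genes sharing the root of a symbol were tested as 309 families with camera, adjusted over the families. In anagen against telogen 24 families were called, among them the late cornified envelope genes Lce, with a median log2 difference of 1.63 (5 of 18 rose, adjusted p 6.67e-08, and adjusted p = 0.42 with an estimated correlation), and the small proline-rich genes Sprr, with 1.55 (6 of 12 rose, 0.000147, adjusted p = 0.409 with an estimated correlation). The replication helicase family Mcm had 1.07 (5 of 10 rose, 3.31e-05, adjusted p = 0.322 with an estimated correlation) and the nuclear pore family Nup 0.72 (4 of 19 rose, 7.44e-07, adjusted p = 0.171 with an estimated correlation). Wnt receptors of the Fzd family had -0.72 (5 of 10 fell, 0.0127, adjusted p = 0.259 with an estimated correlation) and cytochrome P450 genes Cyp -0.38 (12 of 79 fell, 0.00052, adjusted p = 0.636 with an estimated correlation). The Lce family was also higher in HFD against ND 3 months telogen, with 0.84 (0 of 18 rose, 0.03, adjusted p = 0.994 with an estimated correlation), in aged against ND 3 months, with 1.84 (1 rose, 1.8e-07, adjusted p = 0.783) and in aged against ND 4 days, with 1.51 (6.07e-07, adjusted p = 0.996). In aged against ND 3 months 10 families were called, including olfactory receptors Olfr, with 0.51 over 522 genes (3.09e-10, adjusted p = 0.783 with an estimated correlation), vomeronasal receptors Vmn with 0.56 over 91 genes (1.8e-07, adjusted p = 0.783) and hair keratin-associated genes Krtap with 0.59 over 34 genes (0.000233, adjusted p = 0.783). The families Defa (0.61), Ifna (0.69), Pde (0.58), Pramel (0.58) and Tas (0.57) were called higher by like amounts, and Eif lower (-0.25). A rise of this size was thus common to unlike families and not particular to Olfr, Vmn or Krtap. Its cause was not tested. In aged against ND 4 days 1 of 309 families was called, Lce, so Olfr, Vmn and Krtap were not called against this younger group. In HFD 4 days 0 of 309 families were called by camera.

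Whether an anagen array resembles the telogen group of its own condition was tested over the 120 ways of pairing the 5 arrays with the 5 groups, on the correlation across genes after subtracting from each gene its mean over the arrays or groups of the phase. The 5 pairs of 1 condition had a mean r of 0.043 (one-sided exact permutation p = 0.175). The 4 pairs in 1 row of a slide had a mean r of 0.091 (p = 0.025, exact, one-sided), and the 8 pairs on 1 slide 0.1, from 0.042 to 0.179, against -0.047 for the 17 others (p = 0.0333, exact, one-sided; the smallest possible is 0.00833). A signal shared by arrays of a slide is a candidate explanation, and arrays with exchanged labels may give the same picture; these cannot be told apart, since slide, row and condition overlap.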
